A study of Homo sapiens with 3 samples.

How the data were processed

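Total RNA of HEC1B cells, an established human endometrial cancer cell line, was measured in 3 libraries at 48 h. The group "siNC control" holds 1 library labelled siNC. The group "PRMT6 knockdown" holds 2 libraries made with different siRNAs, called siPRMT6-1 and siPRMT6-2. Per the labels' protocols, RNA was purified with a column kit and libraries were made from total RNA with a stranded, low-input total RNA kit. Reads were aligned to hg38 with STAR 2.7.8a and counted with featureCounts 2.0.10, per the submitters' processing notes. Per the file headers, featureCounts was version 2.0.1, exons were grouped by gene name with the UCSC hg38 gene models, pairs were counted, the strand setting was 1, and a read in several overlapping genes was added to each of them. The aligned files named in the header carry a mark of UMI-based removal of duplicates, but how it was done is not given in the sources used here.

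The deposited values are the authors' whole-number counts per gene, with no normalization, for 26485 genes. Column names were matched to the libraries through the descriptions in the labels. The descriptions call the siRNAs si2 and si3 where the titles have siPRMT6-1 and siPRMT6-2, and each per-siRNA value rests on both labels of a sample being right. The totals were 410916 counts in siNC, 381628 in siPRMT6-1 and 362080 in siPRMT6-2. At this depth 3 counts, the floor used for genes at 0, equal 7.77 CPM (depth-scaled counts, with TMM library sizes) in siNC, 8.09 CPM in siPRMT6-1 and 9.09 CPM in siPRMT6-2. Intervals are at 95%, exact Poisson for a count and exact binomial for a ratio of 2 libraries, and they cover counting error only. A test on the counts of 2 libraries compares those libraries, not the conditions. Nothing in the labels says that the libraries came from separate cultures, so the p-values measure only the spread between these libraries.

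Strand affects what a count means here. Genes that share exon bases with a gene on the opposite strand made up 13.6% of the genes and held 51.3% of the counts in siNC, 49.2% in siPRMT6-1 and 47.6% in siPRMT6-2. Among 163 genes with an antisense name that share at least 100 exon bases with their partner and have at least 100 counts over the pair and the 3 libraries, 132 had more counts than the partner in siNC. VIM-AS1 had 12493 counts in siNC and VIM, which encodes an abundant intermediate filament protein, had 312. Counts of genes with an opposite-strand partner are therefore uncertain. The counts of genes called by each tool, with a fold of 2 or more with both siRNAs and with a fold of at least 4 were repeated without them. If reads were counted on the strand opposite to the transcripts throughout, the counts of all genes would be affected, also those without a partner. In 75 pairs the antisense-named gene had at least 100 counts in siNC. There the partner's counts per exonic base were compared with all counts of the antisense-named gene divided by the shared bases. The median was 0.68% (quartiles 0.23 to 1.22%). Antisense counts outside the shared bases and the choice of pairs by antisense counts both lower this share. Some of the 163 pairs went the other way, such as PCED1B-AS1 with 1 count and PCED1B with 1030 in siNC. Opposite-strand exons were taken from the gene models in the deposited table, and overlap with coding genes was also looked up in GENCODE release 29 for the genes named here. Near-identical genes, such as the HLA class I genes, the CCL3L family and the histones, can share reads and are uncertain too.

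The main test was the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with the edgeR 4 estimate of the dispersion, TMM normalization and filterByExpr (a minimum count of 10, a minimum total of 15). It kept 6803 genes and set both PRMT6 knockdown libraries against the siNC library, two-sided, with a Benjamini-Hochberg adjusted p under 0.05. The fit had 1 residual degree of freedom, which is the spread between the 2 siRNAs, and a prior of 12.8 degrees of freedom. A separate edgeR estimate gave a common biological coefficient of variation of 31.6%. The simulations below took their fitted dispersion from the trend of that estimate. The lone control library was assumed to vary like the knockdown libraries. Since the smallest group is a lone library, the filter also kept genes with enough counts in only a single library. Fold changes per siRNA are log2 CPM differences with a prior count of 2. The fold changes of both siRNAs share their control, so 100 sets of 3 libraries without effects were simulated, with the fitted dispersion and with counting error alone. The only control cannot be split, so part of any excess over chance can come from it.

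The test was checked on 5 simulated sets of the 6803 genes, each with 100 genes changed 4-fold and 100 changed 16-fold. It recovered 27.2% of the 4-fold and 78% of the 16-fold changes, and on average 6 calls were false, 5.4% of the calls. Each changed gene had the same fold in both knockdown libraries, so recovery of changes that differ between the siRNAs was not checked. Genes of like expression were also given the same dispersion. Recovery can be lower, and the share of false calls different, where dispersion varies between genes.

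Gene lists, tests, the rule for named genes and most alternatives were fixed before the data were examined. The lists were interferon-stimulated genes, interferon receptors and signalling, interferon ligands, nucleic acid sensing, MHC class I antigen presentation, pro-apoptotic genes, anti-apoptotic genes, p53 target genes, genes reported as PRMT6-repressed, protein arginine methyltransferases, chromatin modifiers, DNA replication, mitosis, replication-dependent histones, the integrated stress response, endoplasmic reticulum chaperones, NF-kappaB and inflammatory genes, immediate early genes, YAP target genes, the TGF-beta response, epithelial genes, mesenchymal genes, endometrial and steroid hormone genes, cholesterol biosynthesis, glycolysis and hypoxia, mitochondrially encoded genes, nuclear oxidative phosphorylation, ribosomal proteins, structural noncoding RNA, nuclear long noncoding RNA, autophagy and lysosome, and leukocyte, fibroblast and endothelial markers. Lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists. They were tested again with an estimated correlation. That estimate rests on 1 residual degree of freedom, so a list that does not pass with it is not argued against. Per siRNA, a list's median log2 fold change was ranked among 10000 random lists of the same size matched on mean expression in 20 bins. PRMT6, CDKN1A, THBS1 and IFNB1 were always named. The 10 genes with the largest rise and the 10 with the largest fall by the smaller of both siRNAs' fold changes were named among genes with at least 100 counts, leaving out symbols of small or unnamed RNAs. Up to 3 members of each list called by camera, and of the interferon-stimulated, apoptotic and p53 lists, were added by the same measure. A few genes that the rule names are not reported here. A gene named outside this rule was chosen after its values were seen.

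Alternatives were RLE or upper-quartile factors, no filter or a CPM of at least 1 in at least 2 libraries, a prior count of 0.5 or 5, leaving out either knockdown library, edgeR's older quasi-likelihood fit, its likelihood ratio test and DESeq2 1.42.0. Chosen after seeing the data were the runs without genes that share exon bases with an opposite-strand gene, and the count of genes with a fold of at least 4 and at least 30 counts in the higher of the knockdown and control libraries. Strand checks and plots used Python 3.11.15.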

Results

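RNA was counted in 3 libraries of HEC1B endometrial cancer cells at 48 h, 1 with the siNC control and 2 with siRNAs against PRMT6, an arginine methyltransferase of histones and other proteins. The libraries held 410916, 381628 and 362080 counts for siNC, siPRMT6-1 and siPRMT6-2. At least 10 counts were reached by 5754, 5679 and 5512 genes in the same order. With 1 library per siRNA and 1 control, no value has a replicate of its own siRNA. In 132 of 163 pairs of an antisense-named gene and its opposite-strand partner, the antisense-named gene had more counts in siNC, so which strand a count stands for is uncertain.

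**Figure D1:**
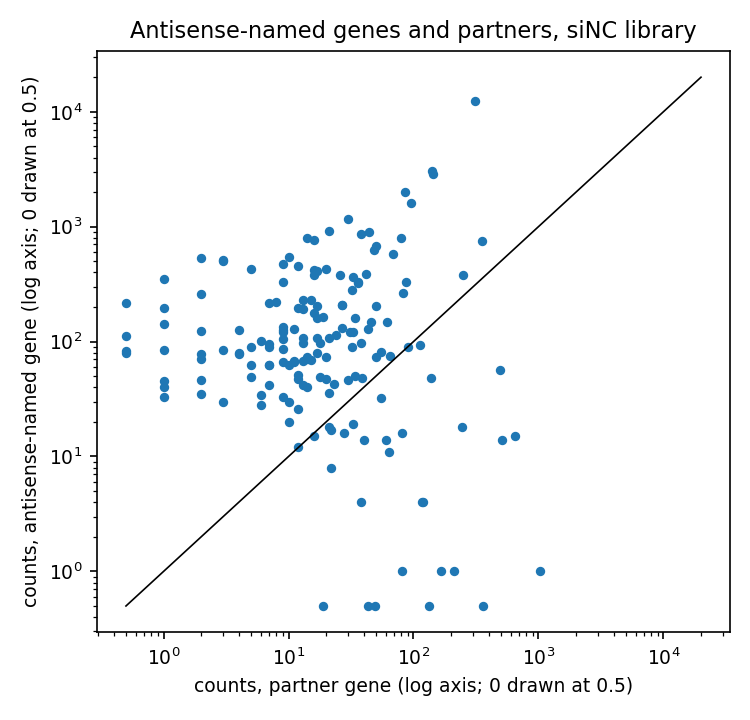
Counts in the siNC library, on log axes, of 163 antisense-named genes (y axis) and the opposite-strand partners with which they share exon bases (x axis), with 0 drawn at 0.5; each point is 1 pair and the line marks equal counts. In 132 pairs the antisense-named gene has more counts.

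PRMT6 was lower in both knockdown libraries. The gene (hg38 chromosome 1, 107056645 to 107059296, plus strand) had 25 counts in siNC (95% exact Poisson interval 16.2 to 36.9), 4 in siPRMT6-1 (1.09 to 10.2) and 7 in siPRMT6-2 (2.81 to 14.4). Relative to siNC its CPM was 0.167 with siPRMT6-1 (exact binomial interval 0.0421 to 0.482) and 0.327 with siPRMT6-2 (0.119 to 0.778). The levels with the 2 siRNAs were not distinguishable at this depth, with a ratio of siPRMT6-2 to siPRMT6-1 of 1.97 and an interval of 0.4997 to 9.157. In the edgeR quasi-likelihood test the log2 fold change was −2.01 (SE 0.684) and the adjusted p was 1.00, so PRMT6 did not pass the test over all genes. No gene of the count table shares exon bases with it on the opposite strand. Its counts would still be affected if reads were counted on the strand opposite to the transcripts throughout.

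The comparison of PRMT6 knockdown with the siNC control asked which genes respond to loss of PRMT6. The edgeR quasi-likelihood test called 0 of 6803 genes, with a lowest adjusted p of 1.00. At an unadjusted p under 0.05 there were 186 genes, 138 higher and 48 lower, where 340 are expected by chance. DESeq2 called 0 genes, and 13 at an unadjusted p under 0.05. The older quasi-likelihood fit of edgeR called 32 genes and its likelihood ratio test 31, all higher in knockdown, with 29 in common. Refitted without genes that share exon bases with an opposite-strand gene, a choice made after seeing the data, these called 0 and 12 genes. Of the 32 genes 23 share no such bases, and their median log2 fold change was 7.64 before and 7.61 after, while the prior degrees of freedom of the older fit went from infinite to 20.3. Of the 32 genes, 18 are in the list of interferon-stimulated genes, all 32 had a fold of at least 4 with siPRMT6-2, and 2 had a fold of at least 2 with siPRMT6-1.

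Interferon-stimulated genes were high in the siPRMT6-2 library. These genes are induced by interferons and many restrict viruses. Their summed counts were 482 in siNC, 562 in siPRMT6-1 and 4248 in siPRMT6-2, which is 1.21 times siNC with siPRMT6-1 (exact binomial interval 1.07 to 1.37) and 10.3 times with siPRMT6-2 (9.37 to 11.3). The 2 knockdown libraries differed by 8.49 times (7.77 to 9.29). The median log2 fold change of the 42 tested members was 0.01 with siPRMT6-1, at percentile 48.6 of matched random lists, and 3.43 with siPRMT6-2, at percentile 100. With genes at 0 set to their bound, the medians were 0.00 and 3.39. A fold of at least 4 was reached by 0 members with siPRMT6-1 and 36 with siPRMT6-2. The list rose in camera with the preset correlation and did not pass with an estimated correlation. That estimate rests on 1 residual degree of freedom, so the second result decides nothing. None of the 42 members passed the quasi-likelihood test over all genes, and 29 passed when adjusted over the list alone. Of these members 14 had 0 counts in both siNC and siPRMT6-1, which sets their fitted value to 0 and holds the siPRMT6-1 median near it. These 14 passed the filter only through their counts in siPRMT6-2. That selection raises the siPRMT6-2 median and the number of members with a fold of at least 4 with siPRMT6-2. It also enters the siPRMT6-2 percentile, the camera result and the passes over the list alone. These are therefore no separate support for an effect shared by both siRNAs. Of the other 28, 21 were higher and 7 lower than siNC with siPRMT6-1, with a median of 0.57, against 2.72 with siPRMT6-2. A value of 0.57 is that of a gene with 0 counts in siNC and 1 in siPRMT6-1, such as IFIT3. The siPRMT6-1 median of these members therefore lies at the floor and by itself cannot show a rise. The summed counts were slightly higher, at 1.21 times siNC, in a comparison of 2 single libraries.

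Among the members named by the rule, HERC6 had 1, 6 and 17 counts in siNC, siPRMT6-1 and siPRMT6-2, PARP12 had 1, 6 and 36, SP110 had 0, 3 and 19, and ISG15, a ubiquitin-like modifier, had 1, 3 and 308. Several others were chosen after their values were seen. IFI6 had 0, 0 and 330 counts, and with siPRMT6-2 it was at least 129-fold higher than the floor of 3 counts in siNC. OAS3, which makes the oligoadenylates that activate RNase L, had 4, 7 and 286 counts, 83.6 times siNC with siPRMT6-2 (32.3 to 309). RSAD2, an antiviral enzyme, had 0, 0 and 67 counts. IFITM3 had 103, 158 and 449 counts, 1.60 times siNC with siPRMT6-1 (1.24 to 2.07) and 5.10 times with siPRMT6-2 (4.11 to 6.38). LY6E went the other way with siPRMT6-1. It had 32, 13 and 185 counts, 0.423 times siNC with siPRMT6-1 (0.204 to 0.828).

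**Figure D2:**
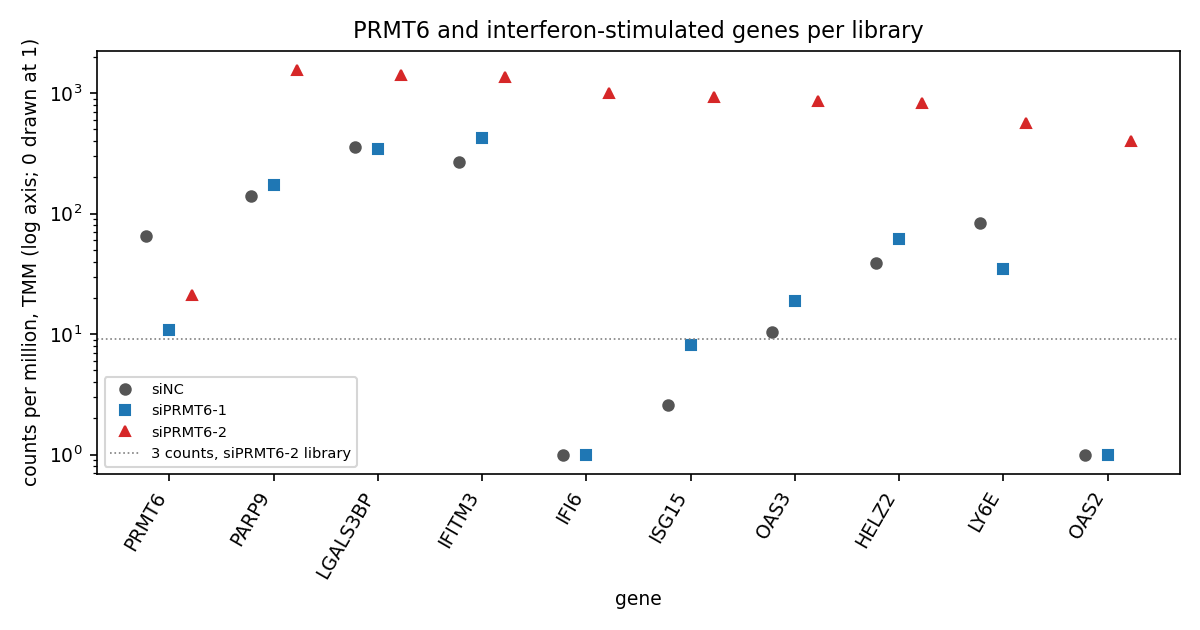
CPM with TMM library sizes on a log axis for PRMT6 and the 9 tested interferon-stimulated genes with the most counts in the siPRMT6-2 library, a choice made after the values were seen; circles are siNC, squares siPRMT6-1 and triangles siPRMT6-2, with 0 drawn at 1. Each point is 1 library, the dotted line is 3 counts in the siPRMT6-2 library, and PRMT6 lies lower in both knockdown libraries while IFI6 has 0, 0 and 330 counts.

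Genes of interferon receptors and signalling, nucleic acid sensing, MHC class I antigen presentation and NF-kappaB and inflammation also rose in camera with the preset correlation. With an estimated correlation none of these 4 lists passed, which decides nothing with 1 residual degree of freedom. In these lists too, the filter could keep members through the siPRMT6-2 library alone. Some members, such as DDX58, are in the interferon-stimulated list as well. For interferon receptors and signalling the medians over 11 tested members were 0.42 with siPRMT6-1 and 1.09 with siPRMT6-2 (camera adjusted p = 0.000441). The named members STAT3, IRF1 and IRF2, all transcription factors, had 4, 10 and 17, 2, 6 and 18, and 6, 11 and 13 counts, and a coding gene overlaps IRF1 on the opposite strand in GENCODE. For nucleic acid sensing the medians were 0.29 and 1.08 over 11 members (camera adjusted p = 0.00435). MB21D1, which encodes the DNA sensor cGAS, had 5, 10 and 8 counts, the RNA sensor gene DDX58 had 7, 12 and 20, and TICAM1 had 6, 8 and 10. For MHC class I antigen presentation the medians were 0.02 and 1.90 over 16 members (camera adjusted p = 1.05e-09), and the summed counts were 619, 591 and 1488. HLA-C had 0, 1 and 62 counts and the immunoproteasome subunit PSMB10 18, 30 and 30. Adjusted over the list alone, 4 of the 16 passed. For NF-kappaB and inflammatory genes the medians were −0.38 and 1.55 over 13 members (camera adjusted p = 0.00128), or 0.00 and 1.72 with genes at 0 set to their bound, and the summed counts were 197, 150 and 479. IL1A had 1, 12 and 6 counts, NFKB1 6, 8 and 22, and RELB 14, 15 and 20. None of these members passed the quasi-likelihood test over all genes. Interferon ligands had 1, 0 and 9 counts in sum, IFNB1 had 0 counts in all 3 libraries, and IFNL1 had 1, 0 and 7.

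**Figure D3:**
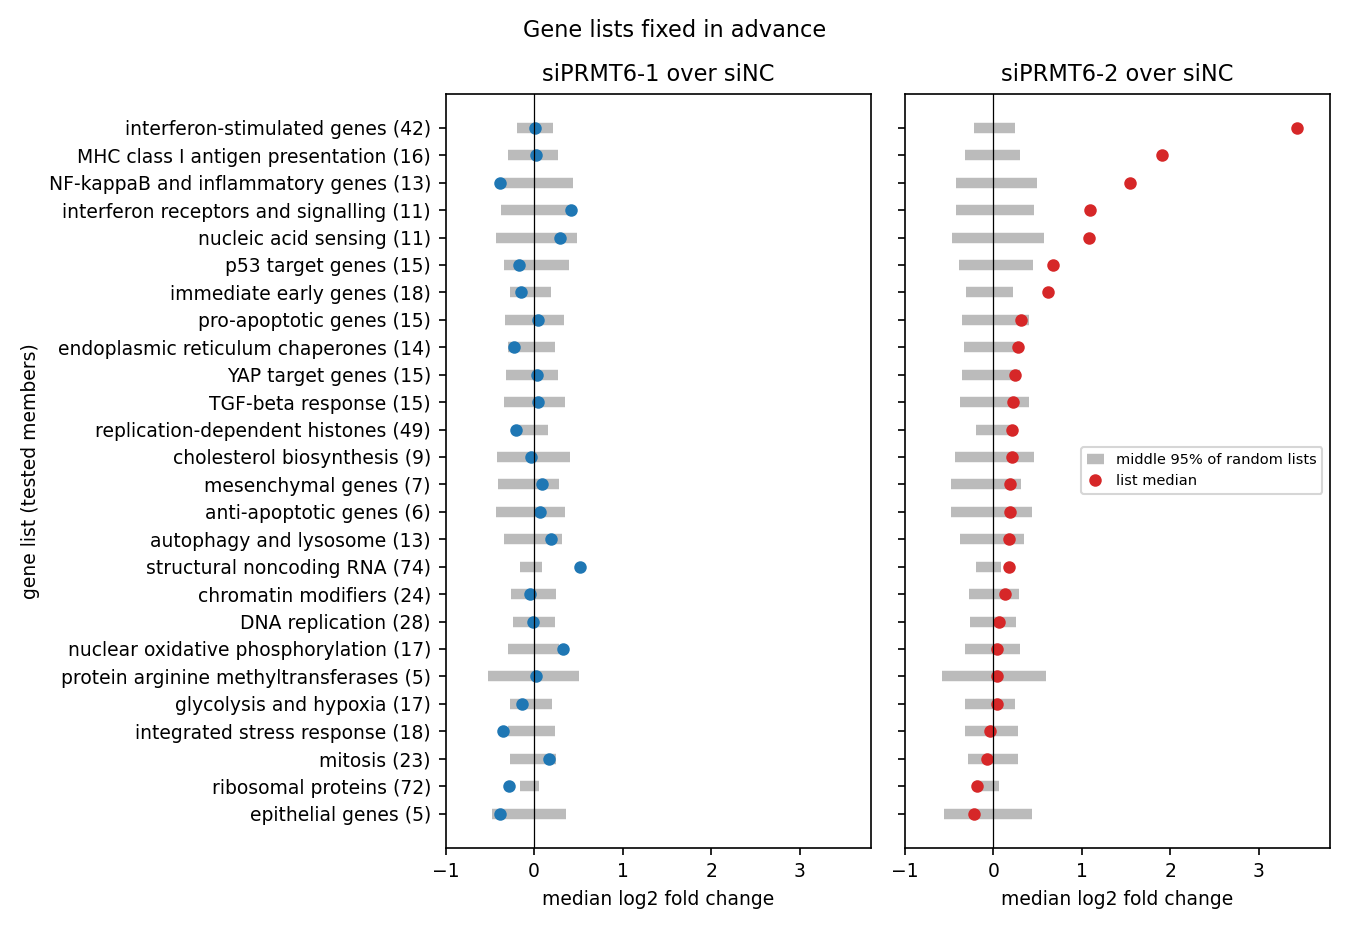
Median log2 fold change over siNC for each gene list with at least 5 tested members, with siPRMT6-1 on the left and siPRMT6-2 on the right; points are list medians and grey bars the middle 95% of 10000 matched random lists. Interferon-stimulated genes have medians of 0.01 and 3.43.

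Ribosomal protein genes fell and structural noncoding RNA rose in camera with the preset correlation. With an estimated correlation neither list passed, which decides nothing with 1 residual degree of freedom. Over 72 ribosomal protein genes the medians were −0.28 with siPRMT6-1 and −0.19 with siPRMT6-2 (camera adjusted p = 0.0126), at percentiles 0 and 3.3 of random lists. RPL23A, which shares exon bases with TLCD1 on the opposite strand, had 59, 37 and 32 counts, RPS26 36, 21 and 20, and RPS10 92, 64 and 34. Over 74 structural noncoding RNAs the medians were 0.51 and 0.17 (camera adjusted p = 0.000133), and SNORD14C had 5, 31 and 19 counts, SNORD50A 11, 27 and 27, and SNORD26 2, 13 and 6. No member passed the quasi-likelihood test. Small nucleolar RNAs lie within host genes, and reads of the host can be counted in them.

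Apoptosis genes did not pass as lists. Pro-apoptotic genes had medians of 0.05 with siPRMT6-1 and 0.31 with siPRMT6-2 over 15 tested members (camera adjusted p = 0.179). Their median over both siRNAs was 0.20, and 0.46 without genes that share exon bases with an opposite-strand gene (camera adjusted p = 0.0946). BBC3, which encodes the BH3-only protein PUMA, had 2, 10 and 15 counts, TNFRSF10A 10, 15 and 16, and BID 8, 12 and 10. BBC3 was 5.20 times siNC with siPRMT6-1 (exact binomial interval 1.11 to 48.8) and 8.77 times with siPRMT6-2 (2.04 to 79.0). TNFSF10, which encodes the death ligand TRAIL and was chosen after its values were seen, had 4, 1 and 26 counts. Anti-apoptotic genes had medians of 0.06 and 0.18 over 6 members (camera adjusted p = 0.853), and CFLAR had 113, 122 and 129 counts and BAG3 29, 39 and 27. CFLAR shares exon bases with CFLAR-AS1 on the opposite strand. The p53 target genes had medians of −0.17 and 0.67 over 15 members (camera adjusted p = 0.406), at percentiles 13.6 and 99.8 of random lists, with TP53I3 at 3, 14 and 8 counts and PLK3 at 5, 13 and 12. TP53I3 shares exon bases with FAM228B on the opposite strand and PLK3 with TCTEX1D4.

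Genes reported as repressed by PRMT6 had 61, 38 and 52 counts in sum. The cell cycle inhibitor gene CDKN1A had 8, 5 and 12 counts and THBS1, which encodes a matrix glycoprotein, had 42, 27 and 21, and FSIP1 overlaps THBS1 on the opposite strand in GENCODE. CDKN1A was 0.650 times siNC with siPRMT6-1 (0.167 to 2.25) and 1.75 times with siPRMT6-2 (0.659 to 4.95), so no difference was detectable at this depth. The protein arginine methyltransferases had medians of 0.02 and 0.04 over 5 members (camera adjusted p = 0.889), with PRMT1 at 60, 47 and 53 counts and PRMT5, which shares exon bases with PRMT5-AS1 on the opposite strand, at 14, 23 and 24.

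None of the other lists passed in camera. Median log2 fold changes with siPRMT6-1 and siPRMT6-2 were −0.05 and 0.13 for chromatin modifiers, −0.01 and 0.07 for DNA replication, and 0.17 and −0.08 for mitosis. They were −0.14 and 0.62 for immediate early genes (camera adjusted p = 0.0834, percentiles 18.0 and 99.99), −0.35 and −0.03 for the integrated stress response, and −0.22 and 0.28 for endoplasmic reticulum chaperones. YAP target genes had 0.03 and 0.25, the TGF-beta response 0.05 and 0.22, epithelial genes −0.39 and −0.21, and mesenchymal genes 0.08 and 0.19. Cholesterol biosynthesis had −0.04 and 0.21, glycolysis and hypoxia −0.14 and 0.04, nuclear oxidative phosphorylation 0.33 and 0.04, and autophagy and lysosome 0.20 and 0.18. Replication-dependent histones had −0.21 and 0.21. Too few members were tested in the remaining lists. Nuclear long noncoding RNA had 259, 487 and 272 counts in sum, and endometrial and steroid hormone genes 245, 221 and 355. Leukocyte markers had 24, 26 and 66 counts in sum, of which CD68 had 17, 19 and 56, while the leukocyte gene LYZ had 0, 0 and 1. Fibroblast markers had 540, 368 and 379 counts and endothelial markers 33, 30 and 18. Mitochondrially encoded genes were not analysed here.

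The second comparison asked how far the 2 siRNAs moved the same genes. B4GALT5, a galactosyltransferase gene, had 36, 76 and 97 counts, 2.20 times siNC with siPRMT6-1 (1.46 to 3.36) and 3.15 times with siPRMT6-2 (2.13 to 4.76). ZFP91 had 25, 44 and 49 counts, FOSL2, an AP-1 subunit gene, 30, 51 and 78, the RNA helicase gene MOV10 32, 54 and 68, and RBM4 42, 71 and 62. Lower with both siRNAs were ST7L with 770, 326 and 211 counts, the semaphorin gene SEMA3F with 66, 32 and 19, the bicarbonate transporter gene SLC4A5 with 177, 91 and 63, and the adenosine receptor gene ADORA1 with 58, 31 and 15. ST7L was 0.441 times siNC with siPRMT6-1 (0.386 to 0.502) and 0.320 times with siPRMT6-2 (0.274 to 0.373), and the coding genes CAPZA1 and WNT2B overlap it on the opposite strand in GENCODE, as MTHFD2 does SLC4A5 and RBM4B does RBM4. None of these genes passed the quasi-likelihood test.

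Further genes chosen by the rule share exon bases with an opposite-strand gene. Higher with both siRNAs were NR1H3, which overlaps ACP2, with 35, 70 and 83 counts, DNAH17, which overlaps DNAH17-AS1, with 19, 59 and 29, and PSMB8-AS1, which overlaps TAP1, with 42, 80 and 844. Lower were HCG25, opposite VPS52, with 138, 62 and 56, SLC3A1, opposite PREPL, with 65, 22 and 29, and FAM229B, opposite TUBE1, with 58, 29 and 24. C22orf23, opposite POLR2F, had 108, 32 and 50 counts, TXNDC5, opposite BMP6, had 58, 16 and 28, and SNHG22, opposite MYO5B, had 62, 18 and 30.

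A fold of 2 or more with both siRNAs was seen in 176 of 6803 genes, 125 higher and 51 lower. Independent lists would share 27.17 higher and 16.03 lower genes. Simulated libraries without effects, which share the control, gave 237 higher (209 to 281) and 146 lower (110 to 170) with the fitted dispersion, and 40.7 (27 to 56) and 14.8 (8 to 24) with counting error alone. Among the 1902 genes with at least 100 counts, 2 were higher and 2 lower. In the simulations these were 45.6 (32 to 61) and 27.6 (16 to 43) with the fitted dispersion, and 0.09 and 0 with counting error alone. The fitted dispersion takes in the gap between the 2 siRNAs, so it can overstate chance. The correlation of the fold changes across genes, which are not independent replicates, was 0.31 (Spearman 0.31), against 0.49 (0.47 to 0.52) and 0.47 (0.44 to 0.50) in the simulations. The covariance was 0.14, against 0.28 and 0.094. Among the 1902 genes the correlation was 0.18 and the covariance 0.050, against 0.50 and 0.225 with the fitted dispersion and 0.47 and 0.0286 with counting error alone. The counts and the covariance lay below the simulated ones with the fitted dispersion and above those with counting error alone. The single control could not be split, so part of any excess may come from it.

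**Figure D4:**
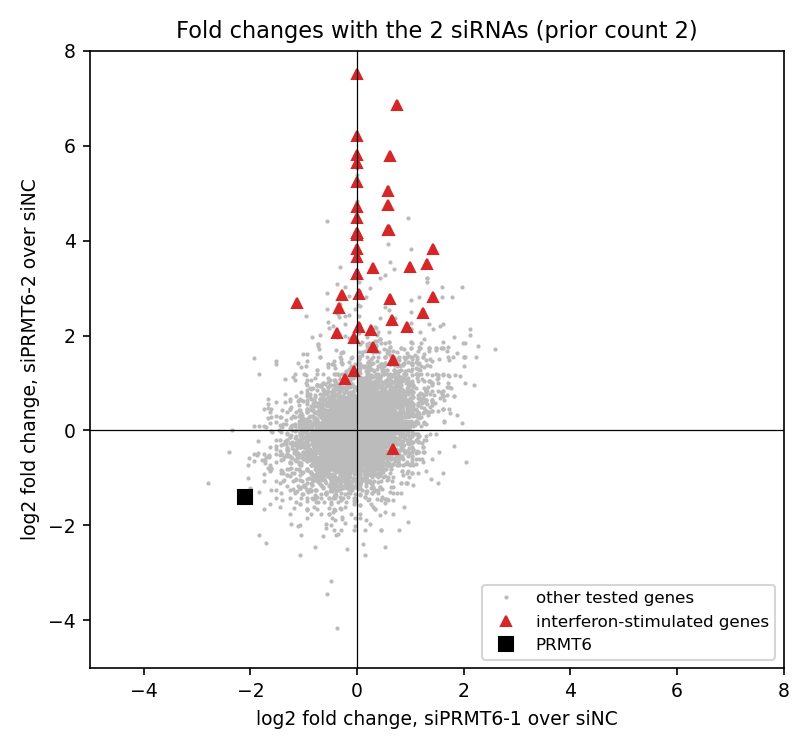
Log2 fold change over siNC with siPRMT6-1 (x axis) and siPRMT6-2 (y axis) for 6803 tested genes, each point 1 gene; triangles are interferon-stimulated genes and the square is PRMT6. The correlation across genes is 0.31, and PRMT6 lies at −2.11 and −1.40.

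Genes with a fold of at least 4 and at least 30 counts in the higher library, a rule chosen after seeing the data, were 2 higher and 0 lower with siPRMT6-1 and 58 higher and 3 lower with siPRMT6-2, with 0 shared. Higher with siPRMT6-1 were SNORD14C and TNFRSF10D, a decoy receptor of TRAIL, which had 16, 70 and 8 counts. Of the 58 genes, 24 are interferon-stimulated genes of the list, and 29 are in it or in a related list. The related lists are MHC class I antigen presentation, nucleic acid sensing, and interferon receptors and signalling. In siNC 17 of the 58 had 0 counts. Of the 38 with a measurable fold with siPRMT6-1, 33 were within 2-fold of siNC. Lower with siPRMT6-2 were CLDN2, a claudin gene, with 36, 26 and 0 counts, LHFPL3 with 59, 40 and 4, and PIGF with 83, 86 and 12. CLDN2 shares exon bases with RIPPLY1 on the opposite strand and PIGF with RHOQ, and without genes of this kind 44 were higher and 1 lower with siPRMT6-2. These folds compare single libraries and have no replicate check.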

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

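The tests of explanations in this part were chosen after the results were seen. The summed counts of interferon-stimulated genes were 8.49 times as high in the siPRMT6-2 library as in the siPRMT6-1 library by an exact binomial test, which compares 2 libraries. Reads of opposite-strand neighbours are argued against, since the ratio was 8.39 (7.63 to 9.23) over the 52 genes that share no exon bases with one. A response of the same size to PRMT6 loss with either siRNA would put siPRMT6-1 near 10.3 times siNC, and its library was at 1.21 times, but with 1 library per siRNA the spread between cultures is unknown. A deeper loss of PRMT6 with siPRMT6-2 stays open too, since its PRMT6 level was 1.97 times that of siPRMT6-1 with an interval of 0.4997 to 9.157. An effect of PRMT6, an effect of this siRNA apart from PRMT6 and a difference between cultures therefore cannot be told apart, because each siRNA has 1 library.

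Antisense-named genes had high counts in all 3 libraries. Counting on the strand opposite to the transcripts is a candidate explanation for a stranded kit, and 81.0% (74.1 to 86.7) of 163 antisense-named genes had more counts than their partner in siNC. Genomic DNA as the sole source is argued against. Among 18009 genes without an opposite-strand partner, the 1% with the most counts per exonic base held 23.6% of the counts. Libraries with only a part of their reads from genomic DNA could show the same, so such a part cannot be excluded. No biological explanation was tested. The kit's strand was not read from the reads, which were not analysed here, so the explanation stays a hypothesis.

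The count of 0 genes in the quasi-likelihood test of edgeR is the real value. Any of the 3 libraries can stand alone against the other 2, too few choices for a share under 0.05, and the highest of the others was 209 genes with siPRMT6-2 alone. That count restates the gap between siPRMT6-2 and the other 2 libraries.

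The median log2 fold change of NF-kappaB and inflammatory genes was 1.93 higher with siPRMT6-2 than with siPRMT6-1, with medians of −0.38 and 1.55, a difference that was not tested. With genes at 0 set to their bound the medians were 0.00 and 1.72, so the negative median with siPRMT6-1 is not kept. The median of replication-dependent histones was 0.42 higher with siPRMT6-2, at −0.21 and 0.21, and this was not tested either.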

How the results depend on the processing

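The repeats without genes that share exon bases with an opposite-strand gene were chosen after seeing the data, and the other alternatives before. The quasi-likelihood test of edgeR called 0 genes with either other normalization, with either other filter and without opposite-strand genes, and DESeq2 called 0, while the older quasi-likelihood fit called 32 and the likelihood ratio test 31. Without opposite-strand genes these tools called 0 (DESeq2), 0 (older fit) and 12 (likelihood ratio test). In the older fit 23 of its 32 genes stayed in the table with a median log2 fold change of 7.61 in place of 7.64, and its prior degrees of freedom went from infinite to 20.3. The cause of the change in calls was not tested for any tool. Genes with a fold of 2 or more with both siRNAs numbered 509 with no filter, 464 with a CPM of at least 1 in at least 2 libraries and 53 with a prior count of 5, in place of 176. Both filters test more low genes (16244 and 13899 in place of 6803), and the larger prior count shrinks their folds. With 1 siRNA left out, 631 to 921 genes had a fold of 2, since only 1 fold has to pass. The correlation was 0.38 with no filter and 0.39 with the CPM filter, and 0.30 to 0.32 elsewhere. Of the 7 gene lists called by camera, the same 7 passed with RLE factors. With an estimated correlation 0 passed, but that estimate rests on 1 residual degree of freedom and decides nothing. The log2 fold change of PRMT6 was −2.05 to −2.01 in all full fits of the main test, and −2.11 to −1.40 with 1 siRNA alone. The median of interferon-stimulated genes was 0.01 with siPRMT6-1 alone and 3.43 with siPRMT6-2 alone, and that of pro-apoptotic genes 0.05 and 0.31, and the latter was 0.46 over both siRNAs without opposite-strand genes in place of 0.20. With 2 libraries, leaving out either always moves a mean by less than 1 SD, so that yardstick says nothing about stability. The 50 other named genes kept their side of the threshold under every refit, which follows from the 0 genes called in each. Upper-quartile factors moved the median of all genes by 0.049. No paired analysis was possible because the labels give no pairing of the libraries. At this depth and design, 16-fold changes were recovered at 78% and 4-fold changes at 27.2% in simulated data. There depth was not varied and each change was the same in both knockdown libraries, so changes that differ between the siRNAs were not covered. Dispersion did not vary between genes of like expression, so recovery in the real data can be lower. Of the 6803 tested genes, 1902 had at least 100 counts.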

Other observations

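More genes had high counts in the siPRMT6-2 library, most of them outside the lists. A gene outside the lists can still be one that interferon induces. All genes in this part were chosen after their values were seen. PML, which encodes the scaffold of nuclear bodies, had 7, 7 and 66 counts in siNC, siPRMT6-1 and siPRMT6-2. ZC3HAV1, an antiviral zinc finger gene, had 21, 21 and 120 counts, RNF213 71, 105 and 362, and SAMHD1, a dNTP hydrolase gene, 1, 4 and 36. WARS, a tryptophanyl-tRNA synthetase gene that is in the integrated stress response list, had 42, 31 and 206 counts. ACO1, which encodes the cytosolic aconitase and iron regulatory protein, had 10, 11 and 71 counts and TMEM132A, which shares exon bases with SLC15A3 on the opposite strand, 19, 14 and 102. These are counts of single libraries with no replicate check.

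Several genes with high counts in the siPRMT6-2 library share exon bases with a gene on the opposite strand. PARP9 had 54, 64 and 514 counts and its opposite-strand neighbour DTX3L 8, 6 and 61. LOC100294362 had 122, 170 and 1031 counts opposite RNF213, TLDC2 31, 29 and 165 opposite SAMHD1, and LOC541472 1, 0 and 55 opposite the cytokine gene IL6, which had 0, 0 and 2. The chemokine gene CCL5 had 0, 0 and 74 counts, at least 28.8-fold higher with siPRMT6-2 than the floor of 3 counts in siNC. Insulin-like growth factor binding protein genes had 3, 9 and 29 counts for IGFBP1 and 7, 14 and 24 for IGFBP3.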
